A study of Bos taurus with 15 samples.

How the data were processed

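Total RNA of biceps brachii muscle from 15 cattle was measured on 1-colour Agilent bovine oligonucleotide arrays, 1 array per animal. There were 8 animals given prednisolone, a synthetic glucocorticoid, by mouth at 30 mg per head and day for 35 days, and 7 control animals. Replicate numbers are animal numbers, so C20 is control animal 20 and P31 is treated animal 31. Per the labels' protocols, RNA of the controls was extracted with the RNeasy Mini kit, and RNA of the treated animals with TRIzol followed by cleanup with the RNeasy MinElute kit. The treatment text of the control samples does not name prednisolone but the growth promoters Finaplix and Revalor, and Revalor with dexamethasone, itself a glucocorticoid. Each of these 7 samples is itself labelled CONTROL, and the text does not say that any of these animals received them. Group and extraction method therefore coincide, and the trial may coincide with them too. No covariate can separate them.

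The deposited value table holds 1 intensity per spot and array on a linear scale. Per the design text, the slides were scanned at 5 micrometre resolution at sensitivities of 100% and 10%, and Agilent Feature Extraction 9.5 gave a background-subtracted, detrended processed signal. Per the submitters' processing notes, R 2.11.1 was used; the method that brought the arrays to a common scale is not given in the sources used here. The scanner output of the 8 treated arrays was used here too, and per the file headers it came from Feature Extraction 9.5.1.1 and holds the processed intensity, the mean spot and background intensities and detection flags. On the treated arrays the table and the log2 processed signal correlated across spots with r from 0.999789 to 0.999991, where spots are not independent replicates, and the empty cells were exactly the spots that the scanner software had not found. Scanner output of the controls was not used here, so the slides and scan days of the controls are not known here.

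The arrays hold 42990 spots that are not controls, for 21475 probes. The share of spots with a value averaged 80.9% ± 5.23 (SD, n = 7) in controls and 81.1% ± 3.33 (SD, n = 8) in treated animals, with the lowest share, 72.1%, on C17. Values were taken as log2, each array was shifted so that its 75th percentile over the 14324 probes with a value on all 15 arrays was the same, and spots of 1 probe were averaged. Before this shift the 75th percentiles lay between 10.56 and 10.76. A probe was tested when it had at least 3 values per group, which left 20894 probes. Most gene names came from the RefSeq table of the reference, through gene identifiers for 9611 probes, accessions for 3504 and other fields. For 2744 probes only the description in the array annotation gave a name, by similarity to a gene of another species. A further 580 took from the description a symbol that the table does not hold. For 158 the description replaced a record that was only a number, and 22 kept the name of the array annotation. In all, 17002 probes carried a name and 4473 did not. Where the table and the description both gave a symbol (9556 probes), 7982 had the same one. A gene was represented by its brightest probe by mean over the 15 arrays, which gave 15073 tested genes. Of 1469 genes with several probes, 625 had probes that differed in the sign of the group difference. Genome positions are not given, since no genome of a named build was used here.

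Groups were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 for the adjusted p. Errors beside group means are SDs between animals, and intervals are 95% confidence intervals from the fit. The number of arrays limits the precision. Lists of genes were tested with camera (preset correlation 0.01) on the 11143 genes with values on all arrays, with adjustment over the 28 lists tested. Mean shifts of lists use these genes too. Counts of positive and negative members cover all measured members, also those without a value on some array. The same lists were tested with an estimated correlation, with fry, and with an exact permutation test of the mean list score over all 6435 splits (two-sided, smallest possible p = 0.000155). The comparison, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the additions named in this paragraph and the next. The named genes were to include the 6 largest rises and 6 largest falls past the threshold without overlap between groups, of which there were none. They further include a fixed set of glucocorticoid, atrophy and muscle genes, the 2 members of each biological list with the smallest p and the 1 member of each cell marker list with the smallest p. This gave 60 genes; FOXO1, which the rule names, was not measured here.

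Lists of transcripts of testis germ cells, testis somatic cells, thymocytes, thymic epithelium, hepatocytes, adrenal cortex, kidney, brain, mammary gland, and B cells, monocytes and granulocytes were drawn up after the data had been seen. A tissue score is the mean log2 deviation of a list's genes on an array from their mean over all arrays. Alternatives tried were the values as deposited, quantile and cyclic loess normalization, equal medians, 2 filters on dim probes, eBayes with trend, array weights, the exact Wilcoxon test, the first residual component as covariate, the mean of all probes of a gene, and each animal left out in turn. Chosen after seeing the data were the exclusion of C20 and P31, the exclusion of 7 arrays, 3 tissue scores as covariates, and the exact permutation of list scores. The 7 arrays were C17, C20, P26, P28, P30, P31 and P32. C24 and C22 stayed in, though their testis germ cell scores of 2.564 and 2.158 lay above the 1.102 of P30. The fit was tested on simulated data with known changes in 10 runs on 15073 genes. For this comparison it recovered 17% of genes changed 1.5-fold, 50.0% changed 2-fold, 77.2% changed 3-fold and 79.0% changed 4-fold, with 3.8 wrong calls per run. With changes added to the real values after group means had been removed, the recovered shares were 8.8%, 47.8%, 75.0% and 79.6%. Removing the means also takes out the chance error of each group difference, with 0 wrong calls per run. In each run 50 genes were changed per fold. The shares are therefore no estimate of power in the real comparison. In simulated values drawn independently for each gene, a list moved 1.2-fold was called by camera in 9 of 10 runs. A list was called in 1 of 10 such runs in which none was moved. In the data genes of a list were correlated, with an estimate of 0.143 for receptor targets and 0.641 for extracellular matrix. These rates therefore do not carry over to the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.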

Results

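Gene expression was measured in the biceps brachii of 8 prednisolone-treated cattle and 7 control cattle, with 1 array per animal. Group values are mean log2 intensities ± SD, from 7 control and 8 treated animals unless other numbers are given. Between 72.1% and 87.4% of spots had a value on an array. On the treated arrays, between 65.0% and 72.6% of probes lay well above background according to the scanner software.

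The comparison asks how oral prednisolone at 30 mg per day for 35 days alters the muscle transcriptome. No gene passed an adjusted p of 0.05. Among genes that respond to glucocorticoids elsewhere, most were lower in treated animals. The list of these genes gives no direction of response, so the lower values are not read as a response to prednisolone. Thioredoxin-interacting protein (TXNIP), an inhibitor of glucose uptake, measured 11.43 ± 0.48 in treated and 12.25 ± 0.29 in control animals, a log2 difference of -0.82 (95% interval -1.26 to -0.39), and all 8 treated animals lay below the control median. The largest difference among the named genes was in CCL2, a chemokine that attracts monocytes, at 9.93 ± 1.36 in treated and 8.14 ± 1.11 in control animals, 3.47-fold higher, with 7 of 8 treated animals above the control median. Interferon-stimulated and leukocyte transcripts were lower on average in treated animals, and clock and nerve sheath transcripts higher. Each of these list shifts lost its call with an estimated correlation between genes.

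Glucocorticoid receptor targets had 23 of 30 measured members with a negative and 7 with a positive difference, and a mean log2 shift of -0.19. The shift was called by camera (adjusted p = 0.00711), but the adjusted p was 0.666 with an estimated correlation and 0.688 with fry, and the exact permutation p was 0.187. No member passed the test over all genes, and 1, TXNIP, passed when adjusted over the list alone (adjusted p = 0.0339). Pyruvate dehydrogenase kinase 4 (PDK4), which restrains glucose oxidation, differed by -0.95 (95% interval -1.79 to -0.10, adjusted p = 0.993). The kinase SGK1 differed by -0.79 (95% interval -1.39 to -0.19, adjusted p = 0.993) on its brighter probe, whose description names another gene, and by +0.05 on its other probe. FKBP5, an immunophilin of the receptor complex, differed by -0.19, the anti-inflammatory mediator TSC22D3 by -0.32 (7 control and 7 treated animals), glutamine synthetase (GLUL) by -0.23 and the transcription factor KLF9 by -0.21, with KLF9 below the control median in 8 of 8 treated animals. FKBP5 ran from -0.37 without C22 to -0.0068 without C18, GLUL was at -0.13 without C17 and -0.15 without P26, KLF9 at -0.13 without C18 and TSC22D3 at -0.20 without P25. The sign for FKBP5 turned to 0.03 with array weights and to 0.15 with tissue scores as covariates. With array weights KLF9 was at -0.0583, TSC22D3 at -0.0376 and GLUL at -0.10, and with the mean of all probes SGK1 was at -0.37. Without C18 the shift of the list was -0.10 and no longer called, and without C20 it was -0.15 and no longer called. Array weights (-0.12), tissue scores as covariates (-0.14) and the exclusion of C20 and P31 (-0.18) also ended the call. Over 31 alternatives its adjusted p ran from 9.83e-05 to 0.699.

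**Figure D1:**
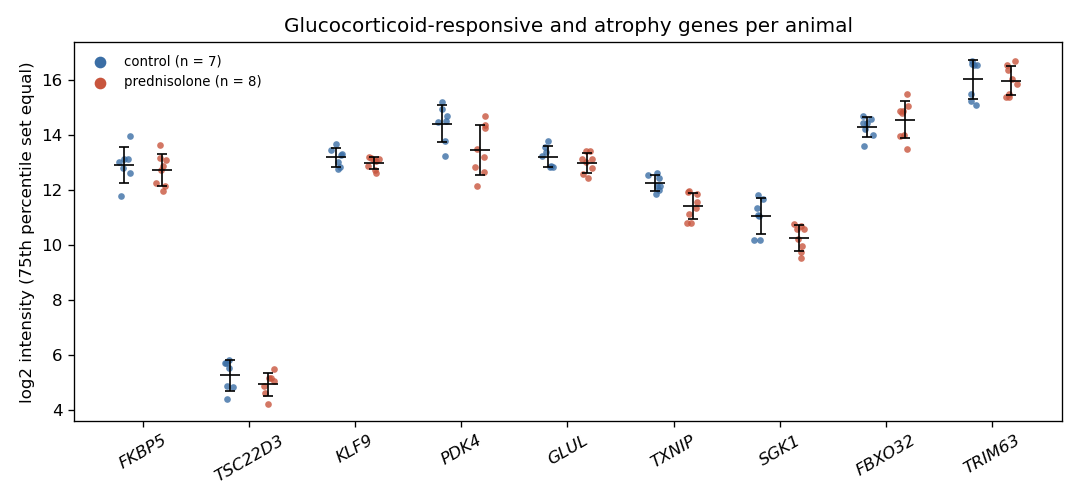
Log2 intensity (75th percentile set equal) of glucocorticoid-responsive and atrophy genes, 1 point per animal, with horizontal lines for the mean and bars for the SD of 7 control and 8 prednisolone animals. TXNIP lies at 12.25 in controls and 11.43 in treated animals, and FKBP5, FBXO32 and TRIM63 overlap widely.

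Glucocorticoid signalling components had a mean shift of 0.19 (8 of 11 positive, camera adjusted p = 0.172, exact permutation p = 0.0368 and 0.691 after adjustment over the lists), and of 0.11 without C17. The receptor gene NR3C1 was at 11.12 ± 0.31 in treated and 11.16 ± 0.16 in control animals, a difference of -0.038 (95% interval -0.33 to 0.26), and of 0.057 without P28. HSD11B2, which inactivates cortisol, was at 6.03 ± 1.496 in treated and 4.89 ± 0.59 in control animals, a difference of 1.14 that fell to 0.72 without P32. The co-chaperone FKBP4 differed by 0.20, and by 0.13 without C17 and 0.12 without P31.

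Genes of protein breakdown showed no shift that passed the test. The muscle atrophy programme had a mean difference of 0.037 (14 of 23 positive, camera adjusted p = 0.333), from 0.0077 without P32 to 0.068 without C17. The muscle ubiquitin ligase FBXO32 differed by 0.27 (95% interval -0.32 to 0.86), from 0.14 without P32 to 0.43 without P28, and TRIM63 by -0.057 (95% interval -0.71 to 0.60). Myostatin (MSTN), a brake on muscle growth, had values in 4 control and 6 treated animals and lay well above background on 2 of 8 treated arrays, so its difference is not interpreted. TRIM63 was below the control median in 7 of 8 treated animals, with a difference of medians of -0.60. Its difference of means lay between 0.012 and 0.053 without C17, C18, C20, C23, P25, P28 or P29, and fell to -0.22 without C21. Proteasome subunits shifted by 0.0066 (19 of 34 positive, camera adjusted p = 0.944), with PSMC6 at -0.26 (-0.16 without C24), and the test turned to lower with the values as deposited, quantile normalization and cyclic loess. Autophagy and lysosome genes shifted by 0.005 (18 of 32 positive, camera adjusted p = 0.944), with the lysosomal regulator TFEB at 0.26 (0.14 without C20) and the protease CTSS at -0.36. The test of the autophagy list turned in direction with quantile normalization, where its mean was 0.0228, and with cyclic loess, where it was -0.0096.

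Fibre type and energy metabolism also held no list past the test. Fast fibre genes shifted by -0.044 (8 of 10 negative, camera adjusted p = 0.338), from -0.13 without P25 to 0.0535 without C21, with parvalbumin (PVALB) at -0.71, but at -0.23 without P29, -0.45 without C18 and -1.14 without P25. Slow fibre genes had a mean of 0.02, a median of -0.10 and a camera direction of lower (10 of 14 negative, adjusted p = 0.213). MYH7, the slow myosin, differed by -0.10 and myoglobin (MB) by -0.13. Glycolysis and glycogen genes shifted by -0.053 (17 of 23 negative, camera adjusted p = 0.158), with ALDOA at -0.17. Oxidative phosphorylation genes shifted by -0.021 (48 of 78 negative, camera adjusted p = 0.286), though ATP5MF differed by +0.39. Fatty acid oxidation genes shifted by 0.035 (20 of 27 positive, camera adjusted p = 0.338), with the mitochondrial carrier UCP3 at -0.72, and lipid synthesis genes by 0.10 (17 of 21 positive, camera adjusted p = 0.297), with DGAT1 at -0.40 and GPAM at +0.63 (6 control and 7 treated animals). Ribosomal proteins shifted by 0.056 (53 of 76 positive, camera adjusted p = 0.155). The insulin and IGF pathway shifted by 0.077 (16 of 25 positive, camera adjusted p = 0.474), with IGF1 at +0.11 a 95% interval from -0.50 to 0.72, and -0.043 without P25. Myogenic and regeneration genes shifted by -0.0038 (14 of 25 negative, camera adjusted p = 0.944). Housekeeping genes shifted by -0.042 (12 of 17 negative, camera adjusted p = 0.338), from -0.0725 without P25 to -0.0133 without P29.

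Immune transcripts pointed in different directions. Interferon-stimulated genes had a mean shift of -0.28 (18 of 26 negative), called by camera (adjusted p = 0.000435) but with an adjusted p of 0.666 with an estimated correlation. Shift and tests rest on the 17 of these 26 genes with values on all arrays. The immunoproteasome subunit PSMB8 differed by -0.56 and the viral RNA sensor DHX58 by -0.44, with DHX58 measured in 5 treated animals. Leukocyte markers shifted by -0.26 (20 of 29 negative, camera adjusted p = 0.0102, and adjusted p = 0.71 with an estimated correlation), with the antigen-presenting BOLA-DRB3 at -0.53. Two-sided exact permutation p-values were 0.0981 for interferon-stimulated genes and 0.365 for leukocyte markers. Inflammatory mediators shifted by 0.14 (22 of 34 positive, camera adjusted p = 0.434), with CCL2 at +1.79 (95% interval 0.50 to 3.09, adjusted p = 0.993), while the related chemokine CCL8 had a control mean of 3.31 (6 animals), near background, and is given no difference. Thymocyte transcripts were highest on C17, with a score of 4.14, followed by P30 at 2.84, P32 at 2.50 and C20 at 1.31. The thymocyte and leukocyte lists share CD3D, CD3E, CD3G and CD8A, all highest on C17, so the leukocyte shift is not independent of this pattern. The leukocyte shift was -0.10 without C17, -0.20 without C18, -0.14 without C20, -0.17 without P31 and -0.059 without C20 and P31 together, an exclusion chosen after seeing the data. It was called in none of these. The interferon shift was -0.18 without P31, -0.14 without C20 and P31 and -0.12 without the 7 arrays picked for transcripts of other tissues, the latter exclusions chosen after seeing the data, and not called in any of these. Over 31 alternatives the adjusted p ran from 3.58e-08 to 0.691 for interferon-stimulated genes and from 9.83e-05 to 0.944 for leukocyte markers.

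Cell types around the fibres and the clock were covered by further lists. Clock genes shifted by 0.18 (14 of 16 positive, camera adjusted p = 0.0326, and adjusted p = 0.666 with an estimated correlation), with the clock repressor BHLHE40 at +1.01 and NR1D2 at +0.35 (+0.23 without C17). Nerve and Schwann cell markers shifted by 0.31 (8 of 8 positive, camera adjusted p = 0.0481, and adjusted p = 0.542 with an estimated correlation), with myelin basic protein (MBP) at +0.37. The nerve shift and its tests rest on only 4 of these 8 genes, those with values on all arrays. The clock call ended without C20, C22, C24, P25, P30, P31 or P32, where the shift lay between 0.13 and 0.19. The nerve call ended without C18, C20, C23, C24, P25, P30, P31 or P32, where the shift lay between 0.23 and 0.38, and also with quantile normalization (0.37) and equal medians (0.33). Over 31 alternatives the adjusted p ran from 0.00299 to 0.691 for clock genes and from 0.0187 to 0.691 for nerve markers. Adipocyte markers shifted by 0.28 (11 of 13 positive, camera adjusted p = 0.0686), with the lipid droplet protein CIDEA at +1.03, and smooth muscle and pericyte markers by 0.17 (8 of 11 positive, camera adjusted p = 0.0686), with smooth muscle actin (ACTA2) at +0.56. Endothelial markers shifted by -0.12 (10 of 14 negative, camera adjusted p = 0.0686), with the angiopoietin receptor TEK at -0.39 and below the control median in 8 of 8 treated animals. Extracellular matrix genes shifted by -0.10 (33 of 49 negative, camera adjusted p = 0.0686), with collagen COL1A1 at -0.56 (95% interval -1.53 to 0.41), at -0.84 without P25 and -0.34 without P32. COL8A1, OGN and the cartilage gene PRG4 lay well above background on 0 of 8 treated arrays and are given no fold. Tendon and cartilage markers shifted by 0.04 (camera adjusted p = 0.944), and the test turned in direction with quantile normalization and equal medians while the mean stayed positive (0.083 and 0.061). With array weights the mean of the tendon list was -0.14. Erythrocyte markers shifted by 0.20 (camera adjusted p = 0.424). Immediate early genes shifted by 0.17 (camera adjusted p = 0.286), with IER3 at +0.77 (+0.51 without C18) and CCN2 at +0.42 (+0.26 without C24), and heat shock proteins by 0.11 (camera adjusted p = 0.286), with HSPB6 at +0.43.

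**Figure D2:**
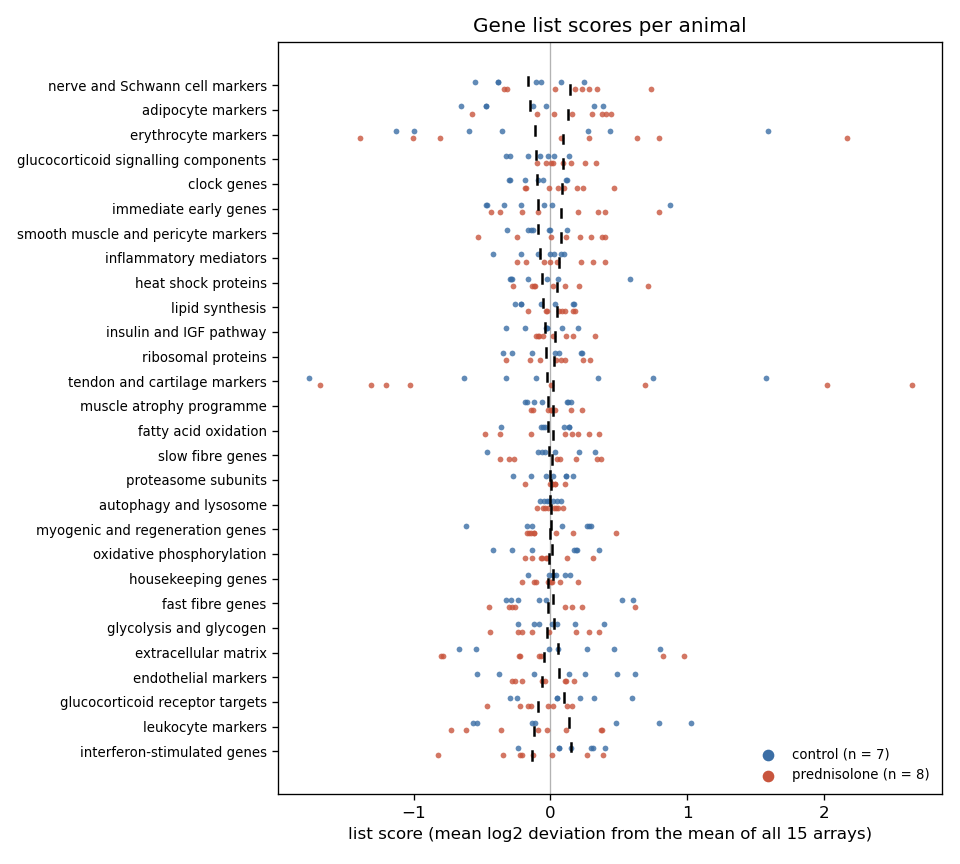
Mean log2 deviation of each gene list from its mean over all 15 arrays, 1 point per animal and a vertical tick for the mean of 7 control and 8 prednisolone animals. Interferon-stimulated genes have group means of 0.15 in controls and -0.13 in treated animals, within the range of single animals.

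Over all 15073 genes, limma called 0, and 487 had an unadjusted p under 0.05 (244 higher and 243 lower in treated animals), where 5% of the genes would be 753.7. The exact Wilcoxon test also called 0 genes, with 416 at an unadjusted p under 0.05. The smallest adjusted p was 0.993. The 95% interval of the group difference had a median half-width of 0.45 log2, and for 73.3% of genes it lay within a 2-fold change in either direction, rising to 89.3% of the 10186 genes well above background on all 8 treated arrays. Groups did not overlap for 30 genes (0.199%), where chance gives 0.272% from the number of values each gene had. They did not overlap for 0 of the 11143 genes with values on all arrays (chance 0.0311%) and for 0 of the 10186 brighter genes (chance 0.0334%). Leaving out 1 animal moved the difference by over 1.5 times, or turned it, for 31 of the 60 named genes. Left out singly, C23 gave 1 call, ZNF696, whose control mean of 2.40 lay near background, so no difference is given. P31 gave 1 call, PZP, well above background on 3 of 8 treated arrays, so the size of its difference is not given. Without C20 and P31 together, PZP was again the 1 gene called, 818 genes had an unadjusted p under 0.05, and camera called 0 lists. ZNF696 and PZP are named because the counts are small, after their values were seen. Adding the first residual component as a covariate gave 326 calls, 323 of them lower in treated animals. Of these, 18 belong to the testis germ cell list and 292 had a correlation over 0.9 with its score across the arrays within groups. The covariate itself followed that score within groups over the 15 arrays (Pearson r = 0.975, Spearman rho = 0.954, two-sided permutation p = 1e-05 for both, the smallest the permutations can give), with r = 0.98 without C20 and P31, so genes that follow the testis score lose spread in that fit by construction. The list was drawn up after the data had been seen and holds PRM1 and TNP1, which lead the first component of the values. These p-values are therefore no separate support. Over all 15 arrays that covariate is unrelated to group by construction, so it left the differences of genes with values on all arrays as they were, while it removed spread within groups.

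The arrays differed more among animals than between groups. The first principal component held 37.3% of the variance (exact permutation p for a group difference 0.204), with PRM1, TNP1 and other genes of sperm formation at its high end. It held 22.7% without C20 and P31. The testis germ cell score was 4.30 on C20, 3.796 on P31, 2.56 on C24, 2.16 on C22 and 1.102 on P30, and -2.75 on P28. It averaged 0.92 ± 2.23 in controls (SD, n = 7) and -0.996 ± 2.31 in treated animals (SD, n = 8), with an exact permutation p of 0.125, 0.896 after adjustment over the tissue lists. PRM1, a protamine that packs sperm DNA, ran from 2.25 on P27 to 17.84 on C20. The second component, with 12.8% of the variance, had the thymocyte gene DNTT at its high end, which was at 13.77 on C17. Hepatocyte transcripts were highest on P26 (2.50) and P28 (2.14). These lists were drawn up after seeing the data. The SD between animals was larger in treated animals for 46.2% of genes, with a median SD of 0.40 in controls and 0.38 in treated animals, and the share was 51.4% without C17 and 56.9% without C20.

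**Figure D3:**
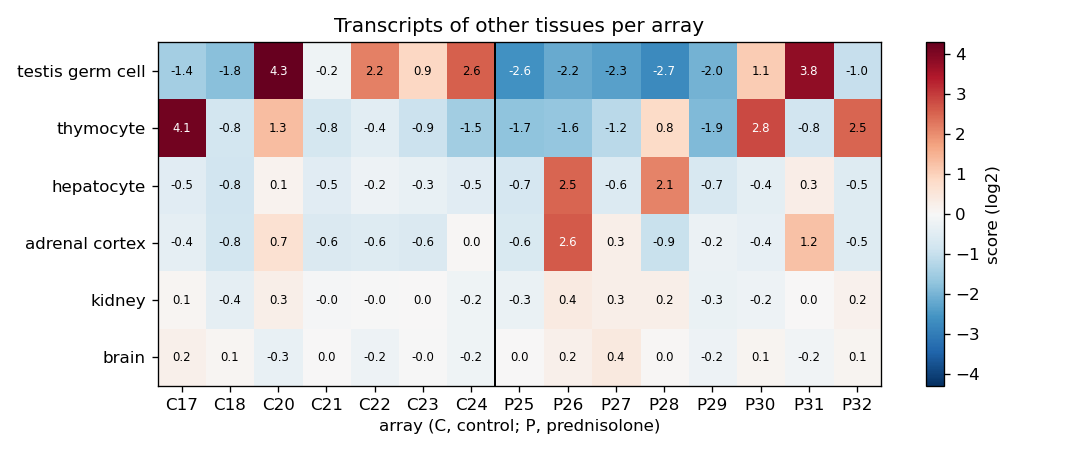
Scores of transcripts of other tissues (mean log2 deviation from all arrays, colour scale in log2) on each array, C for control and P for prednisolone. The testis germ cell score is highest on C20 (4.30) and P31 (3.796), the thymocyte score on C17 (4.14), and kidney and brain scores stay near 0.

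The design text calls the treated animals cows. Of the sex-linked transcripts, ZFY and UTY had values on all 15 arrays, while SRY lay well above background on 0, TSPY on 3 and AMELY on 1 of 8 treated arrays. UTY was at 5.40 ± 0.40 in treated and 5.58 ± 0.45 in control animals, and cross-hybridisation with X-linked relatives was not tested. Within the treated animals, 4 of 21473 probes differed among 3 slides with 2 arrays each, and 1 with another background correction and normalization (normexp and quantile), and 19 differed between the first and the second scan day, and 28 with that other processing. The first scan day held only P25 and P26, the 2 arrays of 1 slide, so day and slide cannot be separated in that comparison. The slides and scan days of the controls are not known here, so the group comparison was not repeated within a slide or day.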

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

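The tissue lists, the tests of prednisolone treatment, of mature T cells and of genes matched in brightness, and the deciding value of the first were chosen after the results were seen. Of 210 groups of values tested, 14 had 1 animal far from the rest of its group, where chance gives about 1 in 20, or 10.5.

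On the testis pattern, P31 stood apart from the other treated animals on the first component (81.1), in its mean correlation with its own group (0.947) and in its testis somatic cell score (0.879), and C20 had the highest 75th percentile as deposited (10.756). Germ cell transcripts were high on C20 and P31, and 9 of the 32 germ cell genes measured lay well above background on all treated arrays. Kidney and mammary gland genes lay 0.197 log2 higher on both arrays than the median of the other arrays, but near the floor (median level 3.21), so they decide nothing about noise of dim probes. The 15 germ cell genes above the floor with values on all arrays lay 5.51 higher, while of 1000 lists of other genes as bright on the other arrays 95% lay less than 0.499 higher, barely under the bound set, and the highest 1.174, which argues against scaling or noise shared by genes of that brightness as the whole cause. The highest control score, that of C20, lay 0.501 above the highest treated score, which argues against prednisolone as the whole cause. C20 is part of the pattern as first seen, so this is no separate test. The exact permutation p for a group difference of the score was 0.125, so a part played by treatment stays open. RNA from testis may be the source and stays open. Testis somatic cell genes, not looked at before, lay 0.964 higher on C20 and P31, short of the 1 set in advance. Of these 7 dim genes, 1 had values on all arrays. INSL3, a bright Leydig cell gene, ran from 5.24 on P28 to 15.11 on P31. It was seen with the pattern and so is no test of it. The design text calls the treated animals cows, and the sex of the animals was not settled here.

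On the thymus pattern, C17 stood apart from the other controls on the second component (71.376) and in its thymic epithelium score (1.241). Genes of immature thymocytes (4 measured, among them DNTT) lay 4.694 log2 higher on C17 than the median of the other arrays. They belong to the thymocyte list, drawn up after the data had been seen, so this is no separate test. As a description of the pattern it argues against mature T cells alone. Genes of B cells, monocytes and granulocytes lay 0.55 higher, between the bounds set in advance, so this score alone cannot tell leukocytes of blood or muscle from other sources. Genes of thymic epithelium, not looked at before, lay 1.44 higher, consistent with RNA from thymus in the sample; of its 5 genes CCL25 peaked on C17 (9.85), while KRT5 (8.11) and KRT14 (8.01) were higher on P32, FOXN1 (5.20) on C24 and PSMB11 (5.55) on C20. The pattern was not confined to C17, since the thymocyte score was also high on P30 (2.837), P32 (2.496) and C20 (1.311). High arrays thus occurred in both groups, and no biological explanation of this was tested.

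Further values in which 1 animal stood apart from its group have no explanation tested here. The score of proteasome subunits was -0.188 on P31, and that of fatty acid oxidation -0.358 on C18. On C23 the heat shock score was 0.586 and the immediate early score 0.876. Log2 intensities were 18.692 for ALDOA on C18, 2.651 for CCL8 on P31, 2.338 for COL8A1 on C23 and 5.753 for MBP on C20.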

How the results depend on the processing

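Chosen after seeing the data were the exclusion of C20 and P31, the exclusion of 7 arrays, the tissue scores as covariates and the exact permutation of list scores. No paired analysis was possible because each replicate number belongs to a different animal. The count of 0 genes past the threshold was kept under every alternative run except the first residual component as covariate, the exclusion of C20 and P31, and the exclusion of C23 or of P31 alone. Where no cause is given, the cause was not tested. Outside the exclusion of single animals, 799 comparisons of a named gene and 365 of a list kept their direction and their side of the threshold. Of the other list comparisons, 30 turned in direction, 38 lost a call and 15 gained one. Of the other gene comparisons, 15 turned and 2 gained a call. The smallest adjusted p of any gene was 0.993 in the main limma fit, so a gene that kept its side says little. The exact Wilcoxon test gave no list values of its own. TXNIP kept its sign in all 29 alternatives, between -0.96 and -0.68, and passed the threshold in 1. Of the 60 named genes, 45 moved by over 1.5 times or turned under at least 1 of the 14 alternatives that left out no single animal: without the 7 arrays PSMB8 fell to -0.0924 and BHLHE40 to 0.41 (0.57 with array weights), CIDEA fell to 0.31 by medians, and PDK4 to -0.43 with tissue scores. Arrays limit these results by signal over background: 674 genes had a difference beyond 2-fold in either direction, of which 90 were well above background on all treated arrays.

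The first residual component as covariate gave 326 genes past the threshold, 279 of them changed at least 2-fold, 1220 at an unadjusted p under 0.05, and 1 list called. TXNIP and HSPA1L were then past it, at log2 differences of -0.82 and -1.33. This covariate removes spread within groups and leaves the group differences of genes with values on all arrays, which is a cause by construction for these; HSPA1L lacks a value and had moved from -1.30. The lists for glucocorticoid receptor targets (-0.19), clock genes (0.18), leukocyte markers (-0.26) and nerve markers (0.31) kept their shifts and lost their calls, and the direction of the test for myogenic genes (-0.0038) turned. Camera with an estimated correlation, fry and the exact permutation each called 0 lists, with the shifts of these lists and of interferon-stimulated genes (-0.28) as before. Fry also gave the opposite direction for myogenic genes.

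Without C20 and P31, 1 gene passed (PZP, near background), 818 genes had an unadjusted p under 0.05, 0 lists were called, and the first component held 22.7% of the variance. The shifts that lost their calls were -0.18 for receptor targets, -0.14 for interferon-stimulated genes, 0.16 for clock genes, -0.059 for leukocyte markers and 0.34 for nerve markers. Turned in direction were proteasome subunits (-0.0105), myogenic genes (0.0033) and TRIM63 (0.0457). Without the 7 arrays, 782 genes had an unadjusted p under 0.05 and 2 lists were called. The calls for interferon-stimulated genes (-0.12), clock genes (0.10), leukocyte markers (-0.069) and nerve markers (0.17) ended, smooth muscle markers were called (0.30), and proteasome subunits (-0.0109), slow fibre genes (0.042), heat shock proteins (-0.15) and MB (0.052) turned.

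With the tissue scores as covariates 9 lists were called, among them extracellular matrix (-0.37), oxidative phosphorylation (-0.096), heat shock proteins (0.21), immediate early genes (0.46), endothelial markers (-0.18) and, turned in direction, ribosomal proteins (-0.092). Receptor targets (-0.14) and nerve markers (0.27) lost their calls. Also turned were proteasome subunits (-0.0373), fast fibre genes in the test (-0.0465), glycolysis (0.12), fatty acid oxidation (-0.047), tendon markers (-0.29), FKBP5 (0.15), HSPA1L (0.42), IGF1 (-0.19) and NR3C1 (0.074).

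Array weights gave 975 genes at an unadjusted p under 0.05. Receptor targets (-0.12), leukocyte markers (mean 0.0123, test still lower) and nerve markers (0.27) lost their calls. Extracellular matrix (-0.17), oxidative phosphorylation (-0.074) and endothelial markers (-0.29) were called. Proteasome subunits (-0.0122), heat shock proteins (-0.033), immediate early genes in the test (0.003), tendon markers (-0.14), FKBP5 (0.0298) and TRIM63 (0.101) turned. The brighter probes only, those above the median probe, gave 260 genes at an unadjusted p under 0.05, with fewer genes tested. Extracellular matrix (-0.11) and smooth muscle markers (0.22) were called, clock genes (0.17) were not, and the test turned for proteasome subunits (0.0028), inflammatory mediators (0.057) and myogenic genes (0.040). Probes above the detection level gave a call for smooth muscle markers (0.22) and a turn for myogenic genes (0.0401).

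Quantile normalization ended the calls for clock genes (0.22) and nerve markers (0.37), gave calls for extracellular matrix (-0.068) and oxidative phosphorylation (-0.0204), and turned proteasome subunits (0.005), autophagy genes (0.0228) and tendon markers (0.083) in the test, and TNNC2 (0.013). Proteasome subunits turned with the values as deposited (-0.0024), cyclic loess (-0.0114) and the mean of all probes (0.0026). Cyclic loess also turned autophagy genes (-0.0096). The mean of all probes turned myogenic genes in the test (-0.0132) and called smooth muscle markers (0.19). Equal medians ended the call for nerve markers (0.33) and turned tendon markers in the test (0.061). Trend and robust eBayes ended the nerve call (0.31). The exact Wilcoxon test, by medians, turned CCN2 (-0.0498), IGF1 (-0.13) and NR3C1 (0.0521). Within the treated animals, normexp with quantile normalization left 1 probe that differed among slides. Correlation of the table with the scanner values fell to 0.991 for mean signal minus background and 0.963 for mean signal.

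Leaving out 1 animal at a time gave 0 to 1 genes past the threshold (ZNF696 without C23, PZP without P31), 0 to 1 changed at least 2-fold, 366 to 1101 at an unadjusted p under 0.05 (1101 without P31), and 3 to 8 lists called. The count of lists was 8 without C17 and 3 without C18, C20, P31 or P32. The share of genes with the larger SD among treated animals ran from 40.7% to 56.9%. Ranges of list shifts were -0.25 to -0.10 for receptor targets, -0.36 to -0.18 for interferon-stimulated genes, -0.37 to -0.10 for leukocyte markers, 0.13 to 0.22 for clock genes and 0.23 to 0.38 for nerve markers. Lists called without some animal were extracellular matrix (-0.25 to 0.029, called without C17, C24, P25 or P26), slow fibre genes (-0.050 to 0.079, P27), glycolysis (-0.11 to 0.0096, C17 or P25), oxidative phosphorylation (-0.091 to 0.039, C18, C20 or P28, turned without C24), heat shock proteins (0.014 to 0.22, C23, turned in the test without P31), immediate early genes (0.073 to 0.34, C23), ribosomal proteins (0.005 to 0.11, C17, C24, P29 or P31), adipocyte markers (0.20 to 0.38, C21, C22 or P31), endothelial markers (-0.22 to -0.033, C17, C20 or P27) and smooth muscle markers (0.13 to 0.26, C22, C23, P26 or P30). Never called, but with a turn of the test without at least 1 animal, were proteasome subunits (-0.0372 to 0.0372), autophagy genes (-0.0066 to 0.0198), fatty acid oxidation (-0.0195 to 0.11), inflammatory mediators (0.077 to 0.20), insulin and IGF genes (0.016 to 0.12), myogenic genes (-0.10 to 0.046), erythrocyte markers (-0.093 to 0.49) and tendon markers (-0.33 to 0.31). Among the remaining lists, fast fibre genes ran from -0.13 to 0.0535, signalling components from 0.11 to 0.23, the atrophy programme from 0.0077 to 0.068, housekeeping genes from -0.0725 to -0.0133 and lipid synthesis from 0.071 to 0.14. HSPA1L was well above background on 4 of 8 treated arrays and was highest on C20 (8.675), P31 (7.803), C22 (6.424) and C24 (6.347). These arrays also had the highest testis germ cell scores. Its turn with tissue scores as covariates therefore says little about heat shock genes. MSTN, near background, gave -0.0207 without C20 and P31, -0.20 with tissue scores, -0.25 by medians and -0.24 to 0.62 without 1 animal, which are not interpreted. Among other genes, IGF1 ran from -0.0425 to 0.27, NR3C1 from -0.084 to 0.057 and TRIM63 from -0.22 to 0.053.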

Other observations

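Adrenal cortex and hepatocyte transcripts were high on single treated arrays. On P26 the adrenal score was 2.63, with the steroid 21-hydroxylase CYP21A2 at 8.64, the 11-beta-hydroxylase CYP11B1 at 6.74, HSD3B1 at 9.97 and STAR, which carries cholesterol into mitochondria, at 8.80. P31 followed at 1.24, with STAR at 8.75 and HSD3B1 at 7.24, and C20 at 0.66. The 2 hydroxylases were not high there: CYP21A2 was at 4.68 on P31 and 4.14 on C20, against a median of 4.75 over all arrays. CYP11B1 was at 3.22 on P31 and 1.75 on C20, against a median of 1.87. CYP11A1 was high on P26 (6.49), P31 (6.86) and C20 (5.91), against a median of 2.13, but also on P27 (5.4). CYP17A1 was at 8.43 on P26, 9.1 on P31 and 8.44 on C20, against a median of 7.85. P31 and C20 therefore show only part of the pattern of P26. They were also the arrays highest in testis germ cell transcripts, and a common source was not tested. Albumin (ALB) was at 9.24 on P26 and 8.84 on P28, against a median of 1.95 over all arrays. Group means were -0.33 ± 0.51 in controls and 0.18 ± 1.201 in treated animals for the adrenal score (SD, 7 and 8 animals, exact permutation p = 0.359), and -0.38 ± 0.30 and 0.24 ± 1.32 for the hepatocyte score (exact permutation p = 0.338). Exact permutation p-values of the other tissue scores were 0.776 for thymocytes, 0.214 for brain, 0.554 for kidney, 0.967 for mammary gland, 0.94 for B cells, monocytes and granulocytes, 0.933 for testis somatic cells and 0.852 for thymic epithelium. After adjustment over the 10 tissue lists these p-values lay between 0.896 and 0.967. BOLA-NC1, a class I histocompatibility gene chosen after its values were seen, ran from 3.57 on P31 to 14.22 on C21.

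The tests of both explanations of the lower glucocorticoid receptor targets, and the split count for genes past the threshold, were chosen after the results were seen. A standard error was added to the test of foreign RNA after its value was known, which made it more cautious. Without the 7 arrays picked for testis, thymus or liver transcripts the shift of the list was larger, -0.2992, and still called by camera (5 control and 3 treated animals left). With 3 tissue scores as covariates it was smaller, -0.1406, and not called. Both sizes meet the bound set for RNA from these tissues not being the cause. However, the 5 controls left include C24 and C22, with testis germ cell scores of 2.564 and 2.158, so the exclusion cannot clear testis RNA. With a standard error of 0.2075 the first size is also not clear of 0, so that explanation stays open. Prednisolone, trial and RNA extraction cannot be told apart. Treatment and extraction follow the group, and the trial may do so too. The treatment text of the controls names the glucocorticoid dexamethasone, though each of them is labelled CONTROL. The exact permutation p of the list score was 0.187.

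Other splits of the 15 animals into 7 and 8 gave results as large as the real one, so chance cannot be excluded for the number of genes at an unadjusted p under 0.05 or of lists called. Among 100 splits including the real one, 61 gave at least as many genes at an unadjusted p under 0.05 (real value 487, highest other 2574) and 75 at least as many lists called by camera (real value 5, highest other 17). For genes past the threshold the count says nothing: with a real value of 0, all 100 splits reach it (highest other 4). Splits with several times the real count point to a structure among the animals. With C20 and P31 in 1 group, 39 splits had a median of 894 genes at an unadjusted p under 0.05, and with C20 and P31 in different groups, 60 splits had a median of 423.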
